A study of Mus musculus with 12 samples.

How the data were processed

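Messenger RNA was sequenced from mouse cells described in the labels as primary cardiac fibroblasts, the matrix-producing cells of the heart. Per the labels' protocols, the fibroblasts were grown in medium with 10% serum, starved for 12 h and then exposed for 24 h to conditioned medium, which is culture medium taken from other cells together with what they released. The other cells were adipocytes infected with lentivirus. Libraries were prepared from 1.3 µg of total RNA with a SMARTER mRNA kit, per the labels' protocols. The adipocytes themselves were not analysed here, so the level of the microRNA could not be checked in them.

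The 12 libraries form 4 groups of 3. VEC_CM received the medium of adipocytes infected with an empty vector, and OE_CM that of adipocytes overexpressing the human microRNA miR-548ay. TGF_VEC_CM and TGF_KD_CM combined TGF-beta1, a growth factor that activates fibroblasts, with conditioned medium. That medium came from vector adipocytes or from adipocytes in which the microRNA was inhibited, respectively. Whether TGF-beta1 was in the medium, added to the fibroblasts or given to the adipocytes was not settled here. Groups were taken from the sample titles, because the treatment labels of replicates 2 and 3 in OE_CM and TGF_KD_CM name miR-549ay and miR-550ay, numbers that run on with the replicate. The labels place VEC_CM and OE_CM in one part of the study and the TGF-beta1 groups in another, and they do not say whether the parts were run together. They also do not say whether the libraries of a group come from separate cultures, so every p-value here measures only the spread between these libraries, which may be technical.

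The deposited table of read counts holds whole-number counts for 24619 gene symbols, with 1 column per library and no normalization. The deposited FPKM table holds the same genes and libraries; in it each count had been divided by the column total and by 1 length per gene, which was checked for all 24619 genes to within 0.01%. Reads were mapped to GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. Genes that share reads with near-identical copies, such as Ifit1, Oasl2, Apol9b, Ly6c1, Gstm1, Fth1 and Ftl1, have uncertain counts for that reason, and overlapping or antisense genes cannot be told apart. Gene positions and NCBI gene numbers come from a RefSeq table of GRCm38, in which 23408 of the symbols (95.1%) were found.

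Library totals ran from 33379207 counts (OE_CM replicate 3) to 37226153 (OE_CM replicate 1). At this depth 3 counts stood for at most 0.0939 CPM (counts scaled to library size) in any library, which is the floor used here; floors cover counting error only. Mitochondrial messenger RNA took between 1.97% and 2.29% of the counts of a library, and the 20 most abundant genes between 7.00% and 7.71%. Within groups, log CPM of replicate pairs correlated across genes with r between 0.992 and 0.994, and the chi-square per gene lay between 2.96 and 4.43, so no pair differed by as little as sampling noise.

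Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 14400 genes and removed 10219; the kept genes held at least 99.9% of the counts of every library. TMM factors were computed and all 12 libraries were fitted in 1 robust quasi-likelihood model with a mean for each group, because the cells and protocol are the same and pairs of groups alone leave few degrees of freedom. The common biological coefficient of variation was 0.0341. Tests were two-sided, with Benjamini-Hochberg adjustment over all 14400 genes and a threshold of 0.05, and genes that also changed at least 2-fold were counted separately. Comparisons were OE_CM with VEC_CM, TGF_KD_CM with TGF_VEC_CM, TGF_VEC_CM with VEC_CM, and the difference between the OE_CM and TGF_KD_CM effects. CPM values are scaled by the TMM factors and given as mean ± SD over the 3 libraries of a group; log2 fold changes are given with their standard error (SE).

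Before the data were examined, 27 gene lists with 590 entries were fixed, of which 572 were in the table. They cover matrix, contractile, TGF-beta, cytokine, interferon, metabolic and stress genes, and markers of other cell types. Each list was tested with limma 3.58.1 camera on log CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 27 lists within a comparison, and again with a correlation estimated per list. Camera asks whether a list moved relative to the other genes. The fry test, an alternative, asks either whether the genes of a list move on balance in one direction or, in its mixed form, whether they change at all, and compares them with no other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone.

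The named genes were also chosen by a rule fixed before the data were examined. For each comparison it takes the 6 largest rises and the 6 largest falls among genes past the threshold with a mean log CPM of at least 2 and with no overlap between the groups' libraries, leaving out gene models without a proper symbol. It adds up to 4 members of lowest p of each list described, or the 2 most abundant where fewer than 2 passed, and 13 preset readouts of fibroblast activation. For the comparison of effects it takes the 5 genes of lowest p moving in opposite directions and the 5 moving in the same direction. Id1, Id2 and Id3, named by the rule in TGF_KD_CM, are given in OE_CM as well. Some genes that the rule takes are not reported here.

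The edgeR tests of pairs of groups, and camera with 1 shifted list, were first tried on simulated counts drawn from the real means and library sizes with 200 genes changed. The simulated spread followed expression level alone, with no differences between genes of the same level. Far more genes were called in the real comparisons, so the shares that follow may not carry over to them. For OE_CM against VEC_CM, edgeR recovered 53.1%, 81.6%, 83.7% and 93.9% of genes with true log2 changes of 0.25, 0.5, 1 and 2, and called 7 of 13927 unchanged genes. For TGF_KD_CM against TGF_VEC_CM the shares were 46.0%, 85.7%, 76.0% and 98.0%, with 15 of 13909 unchanged genes called, which made up 8.98% of the calls. For TGF_VEC_CM against VEC_CM they were 58.0%, 65.3%, 85.7% and 100%, with 7 of 13923. The test of the difference between effects, fry and glmTreat were not tried in this way.

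Alternatives fixed before the data were examined were DESeq2 size factors or upper-quartile factors in place of TMM, no filter or a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, only the groups compared in the fit, the replicate number as a block, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a filter of FPKM 1 in at least 3 libraries or with none, a test against a minimum change of 1.2-fold (glmTreat), and leaving out each library in turn. Comparisons that share a control group were set beside 20 simulated data sets without effects.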

Results

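Gene expression was measured in 12 libraries of mouse fibroblasts, 3 for each of 4 conditioned media. The series asks whether adipocytes that overexpress miR-548ay, or in which it is inhibited, release signals that change gene expression in cardiac fibroblasts. The 4 groups separated along the leading principal components of log CPM, which carried 39.0%, 22.7% and 14.3% of the variance. A further component, with 3.81%, set OE_CM replicate 1 (score 27.8) apart from OE_CM replicates 2 and 3 (scores -14.6 and -12.0). Genes with at least 1 count numbered 18671 to 18815 in VEC_CM, 18212 to 18398 in OE_CM, 19810 to 19972 in TGF_VEC_CM and 19333 to 19406 in TGF_KD_CM, at similar depth.

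**Figure D1:**
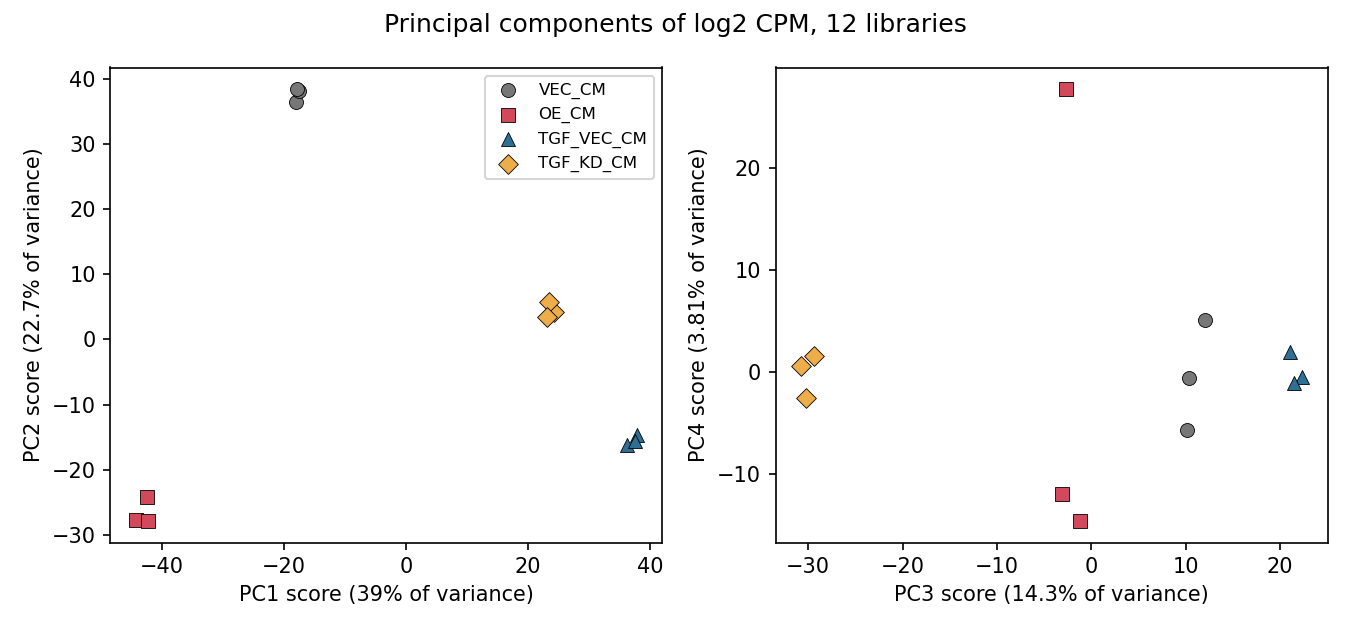
Principal component scores of log2 CPM for the 12 libraries, with PC1 against PC2 on the left and PC3 against PC4 on the right; each point is a library and colours and shapes mark the 4 groups. The groups lie apart on PC1 (39.0% of variance) and PC2 (22.7%), and OE_CM replicate 1 stands apart on PC4 (3.81%).

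Medium from adipocytes overexpressing the microRNA was compared with vector medium to ask what the microRNA in adipocytes changes for the fibroblasts. Smad7, which encodes an inhibitor of TGF-beta signalling that the pathway itself induces, rose 3.61-fold, from 10.3 ± 0.289 CPM in VEC_CM to 37.3 ± 2.31 CPM in OE_CM (SD, n = 3). Of 21 genes of the TGF-beta responsive list 15 rose, and of 20 ATF4 targets, which serve amino acid synthesis and the stress response, 16. Of 22 genes of fatty acid uptake and oxidation 17 fell and 2 rose, though the list calls of these and of the ATF4 targets were lost with an estimated correlation (adjusted p = 0.183 and 0.335). The lipoprotein lipase gene Lpl fell from 682 ± 21.3 to 300.8 ± 2.51 CPM (log2 fold change -1.18 ± 0.025 SE). Of 28 interferon-stimulated genes 12 fell and 2 rose, a list call also lost with an estimated correlation (adjusted p = 0.499).

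The largest rise by the naming rule was that of Hr, the hairless corepressor of nuclear receptors (chromosome 14, 70554056 to 70573548, NCBI gene 15460), at 9.84-fold, from 6.43 ± 0.427 to 63.4 ± 3.94 CPM (log2 3.30 ± 0.066 SE; edgeR adjusted p = 1.02e-47). Olr1, a receptor for oxidised lipoprotein, rose 9.33-fold, Spsb1, an adaptor of a ubiquitin ligase, 7.63-fold, and Zbp1, a sensor of nucleic acids, 7.25-fold. The largest fall by the same rule was that of Itga3, an integrin chain that binds laminin (chromosome 11, 95044475 to 95076844, NCBI gene 16400), from 70.1 ± 5.33 to 8.35 ± 0.803 CPM (log2 -3.07 ± 0.064). Next came Ly6c1 (log2 -2.93), the matrix proteoglycan gene Prelp (-2.91), Mrgprf (-2.82), Glt8d2 (-2.69) and the aldehyde dehydrogenase gene Aldh3a1 (-2.55).

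Of 21 measured TGF-beta responsive genes, 15 rose, 4 fell and 2 did not pass the test (16 and 4 adjusted over the list alone; camera adjusted p = 0.000375, and adjusted p = 0.0497 with an estimated correlation). Skil rose by 1.60 ± 0.036 on the log2 scale, Ldlrad4 by 1.51 ± 0.043 and Smad7 by 1.85 ± 0.071, and all 3 encode inhibitors of the pathway; Ccn4, which encodes a matricellular protein, rose by 1.42 ± 0.027. Among the 4 falls were those of Id1, Id2 and Id3, inhibitors of differentiation (log2 -1.16 ± 0.058, -1.53 ± 0.076 and -1.61 ± 0.066). Among 20 ATF4 targets 16 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.38e-05, but adjusted p = 0.335 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, rose 3.59-fold, Atf4 itself 1.40-fold, and the mitochondrial one-carbon enzymes Shmt2 and Mthfd2 rose 1.39-fold and 1.46-fold. The immediate early genes went both ways, with 5 higher and 6 lower of 21 (the same adjusted over the list alone; camera adjusted p = 0.83). Junb rose by 1.38 ± 0.052 and Myc by 1.15 ± 0.037, while the phosphatase genes Dusp6 and Dusp1 fell by 1.02 ± 0.086 and 1.33 ± 0.12 on the log2 scale.

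Of 22 PPAR targets and genes of fatty acid oxidation, 17 fell, 2 rose and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.000375; adjusted p = 0.183 with an estimated correlation). Beside Lpl (chromosome 8, 68880555 to 68906932, NCBI gene 16956), the oxidation enzymes Acadm, Acaa2 and Ech1 fell by 0.96 ± 0.039, 1.11 ± 0.055 and 0.63 ± 0.04 on the log2 scale. Pparg itself was at 124.7 ± 3.17 CPM in OE_CM and 124 ± 3.25 CPM in VEC_CM (edgeR adjusted p = 0.853). Among 15 adipocyte markers 5 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.345), and the fatty acid carrier Fabp4 fell from 260.5 ± 7.36 to 85.7 ± 2.35 CPM. Of 20 NRF2 targets, genes of the antioxidant response, 10 fell and 5 rose, the same adjusted over the list alone (camera adjusted p = 0.217). Gstm1 fell by 1.28 ± 0.028 and Gsta4 by 1.03 ± 0.052 on the log2 scale. Fth1 fell by 0.60 ± 0.022, while Ftl1, the other ferritin chain, rose by 0.29 ± 0.022.

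Matrix genes moved in both directions. Of 33 collagens and matrix proteins, 16 rose, 12 fell and 5 did not pass, the same adjusted over the list alone; the median log2 fold change was 0.16, the mean -0.07, and the camera direction up (adjusted p = 0.593). Col1a1 rose from 1303 ± 19.4 to 1689 ± 50.3 CPM (log2 0.38 ± 0.022), and Fbn1 and Fbln2, genes of elastic fibre proteins, rose by 0.85 ± 0.026 and 0.73 ± 0.021. Col6a2 fell from 504.7 ± 32.4 to 159.7 ± 4.29 CPM. Fn1 rose by 0.18 ± 0.021. Col3a1 had a log2 fold change of -0.12 ± 0.039 (edgeR adjusted p = 0.00823), a call that was lost without VEC_CM replicate 1 (-0.09) or OE_CM replicate 1 (-0.10). Col1a2 stood at 4427 ± 85.5 CPM against 4379 ± 58.3 CPM and did not pass the test. Postn, at 1.65 ± 0.249 against 1.02 ± 0.0593 CPM, passed it (adjusted p = 0.0161) but not without VEC_CM replicate 1 (log2 0.64) or OE_CM replicate 3 (log2 0.57). Acta2, the smooth muscle actin of myofibroblasts, was at 0.497 ± 0.0725 against 0.592 ± 0.127 CPM (adjusted p = 0.641), and Tagln and Ccn2 were too low to be tested.

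Among 22 genes of collagen processing and crosslinking 9 rose and 5 fell (camera adjusted p = 0.274), with Tgm2 and Loxl2, which encode crosslinking enzymes, 2.23-fold and 2.06-fold higher. Of 19 matrix proteases and inhibitors 7 rose and 6 fell (camera adjusted p = 0.981). Timp1 rose 2.34-fold, while Timp2 and the aggrecanase gene Adamts5 fell by 1.05 ± 0.028 and 1.89 ± 0.11 on the log2 scale. Contractile genes of myofibroblasts had 10 higher and 5 lower of 18 (camera adjusted p = 0.261), among them Pdlim7 and Cald1, which rose by 1.00 ± 0.037 and 0.62 ± 0.022, and Mylk and Cnn2, which fell by 0.98 ± 0.047 and 0.67 ± 0.025. Of 17 markers of resting fibroblasts 5 rose and 8 fell (camera adjusted p = 0.336). Dpt rose 5.66-fold, and Ly6a and Pdgfra fell by 2.36 ± 0.056 and 1.01 ± 0.032 on the log2 scale. These 4 lists gave the same counts adjusted over the list alone.

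In the interferon-stimulated list 12 genes fell, 2 rose and 14 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00924; adjusted p = 0.499 with an estimated correlation). Oas3, Ifit2 and Dhx58 fell by 1.70 ± 0.16, 0.93 ± 0.076 and 1.00 ± 0.12 on the log2 scale, whereas Zbp1, of the same list, rose. Of 13 leukocyte markers 4 fell, none rose and 9 did not pass, also adjusted over the list alone, with Lyz2 at 12.6 ± 2.81 against 22.0 ± 1.68 CPM. That list did not pass camera (adjusted p = 0.0731, and 0.712 with an estimated correlation), though it did without OE_CM replicate 1 (camera adjusted p = 0.00129). Of 26 cytokines and chemokines 9 rose and 6 fell (9 and 7 adjusted over the list alone); their median was -0.04, their mean 0.07 and the camera direction up (adjusted p = 0.593). Lif rose 3.79-fold, Ccl7 2.09-fold, Ccl2 1.90-fold and Csf1 1.57-fold, and Il6 fell from 2.99 ± 0.675 to 1.72 ± 0.27 CPM. Of 22 receptors and signalling genes for adipocytokines 11 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.593); Irs1, the insulin receptor substrate, fell from 171.8 ± 4.13 to 32.7 ± 1.07 CPM and Tnfrsf1b rose 1.96-fold.

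Other stress and metabolic lists moved little or both ways. Endoplasmic reticulum chaperones had 10 lower and 4 higher of 19 (camera adjusted p = 0.128), sterol synthesis genes 9 lower and 3 higher of 21 (0.217) and p53 targets 8 higher and 4 lower of 16 (9 and 4 adjusted over the list alone; 0.146). Hypoxia and glycolysis genes had 9 higher and 7 lower of 23 (9 and 8 adjusted over the list alone; camera adjusted p = 0.943), with Vegfa 2.03-fold and Hk2 1.78-fold higher. Cell cycle genes had 10 higher and 5 lower of 35 (10 and 3 adjusted over the list alone; 0.902) and oxidative phosphorylation genes 7 higher and 2 lower of 22 (6 and 2 adjusted over the list alone; 0.518). Of the cardiomyocyte markers only Tnnt2 rose, from 71.9 ± 3.33 to 162.5 ± 2.23 CPM.

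In all, 7778 of 14400 genes passed the threshold, 4083 higher and 3695 lower in OE_CM, and 1059 of them changed at least 2-fold, 351 higher and 708 lower. The median absolute log2 change of the genes called was 0.325. Upper-quartile factors gave 2798 higher and 5059 lower genes and DESeq2 size factors 4002 and 3767; limma on log2(FPKM + 1), which also changes the test and the filter, gave 2686 and 4068. Only 3078 genes passed a test against a change of 1.2-fold. Among genes changed at least 2-fold, limma on log2(FPKM + 1) called 84 higher and 126 lower. In the main fit the excess of such falls lay in genes with a mean below 16 CPM. Under 1 CPM 134 genes were higher and 304 lower, from 1 to 4 CPM 73 and 191, and from 4 to 16 CPM 51 and 113. At 16 CPM and over 93 were higher and 100 lower.

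Inhibition medium was compared with vector medium in the TGF-beta1 groups to ask what lowering the microRNA in adipocytes changes. The response was led by interferon-stimulated genes, of which 27 of 28 rose. Ifi44 rose about 100-fold, from 1.27 ± 0.256 CPM in TGF_VEC_CM to 127.9 ± 2.17 CPM in TGF_KD_CM (SD, n = 3; log2 6.65 ± 0.084 SE), and Bst2, the gene of tetherin, from 44.1 ± 1.66 to 284.2 ± 7.71 CPM. Smad7 fell from 23.5 ± 1.56 to 13.9 ± 0.12 CPM (log2 -0.76 ± 0.07). Among TGF-beta responsive genes, immediate early genes and genes of endoplasmic reticulum chaperones more fell than rose, and among PPAR targets and sterol synthesis genes more rose than fell, though these 5 list calls were lost with an estimated correlation (adjusted p = 0.151, 0.151, 0.621, 0.293 and 0.621).

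The interferon-stimulated list had a median log2 fold change of 3.51; 27 genes rose over all genes tested and adjusted over the list alone, and 1 did not pass (camera adjusted p = 9.17e-22; adjusted p = 0.021 with an estimated correlation). Ifi44 lies on chromosome 3 (151730922 to 151749910, NCBI gene 99899) and Bst2 on chromosome 8 (71534255 to 71537472, NCBI gene 69550). Oas2, which encodes a synthetase activated by double-stranded RNA, rose 53.5-fold, the ubiquitin-like Isg15 49.2-fold, Usp18, which removes Isg15 from proteins, 29.8-fold, and Xaf1 23.4-fold. Ifit1 rose 50.5-fold and Oasl2 40.3-fold, with the uncertainty of genes that have close copies. Leukocyte markers did not rise alongside: of 13, 1 was higher and 2 lower, also adjusted over the list alone (median log2 -0.38; camera adjusted p = 0.558), and Lyz2 was at 14.8 ± 1.01 against 20.3 ± 0.995 CPM.

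**Figure D2:**
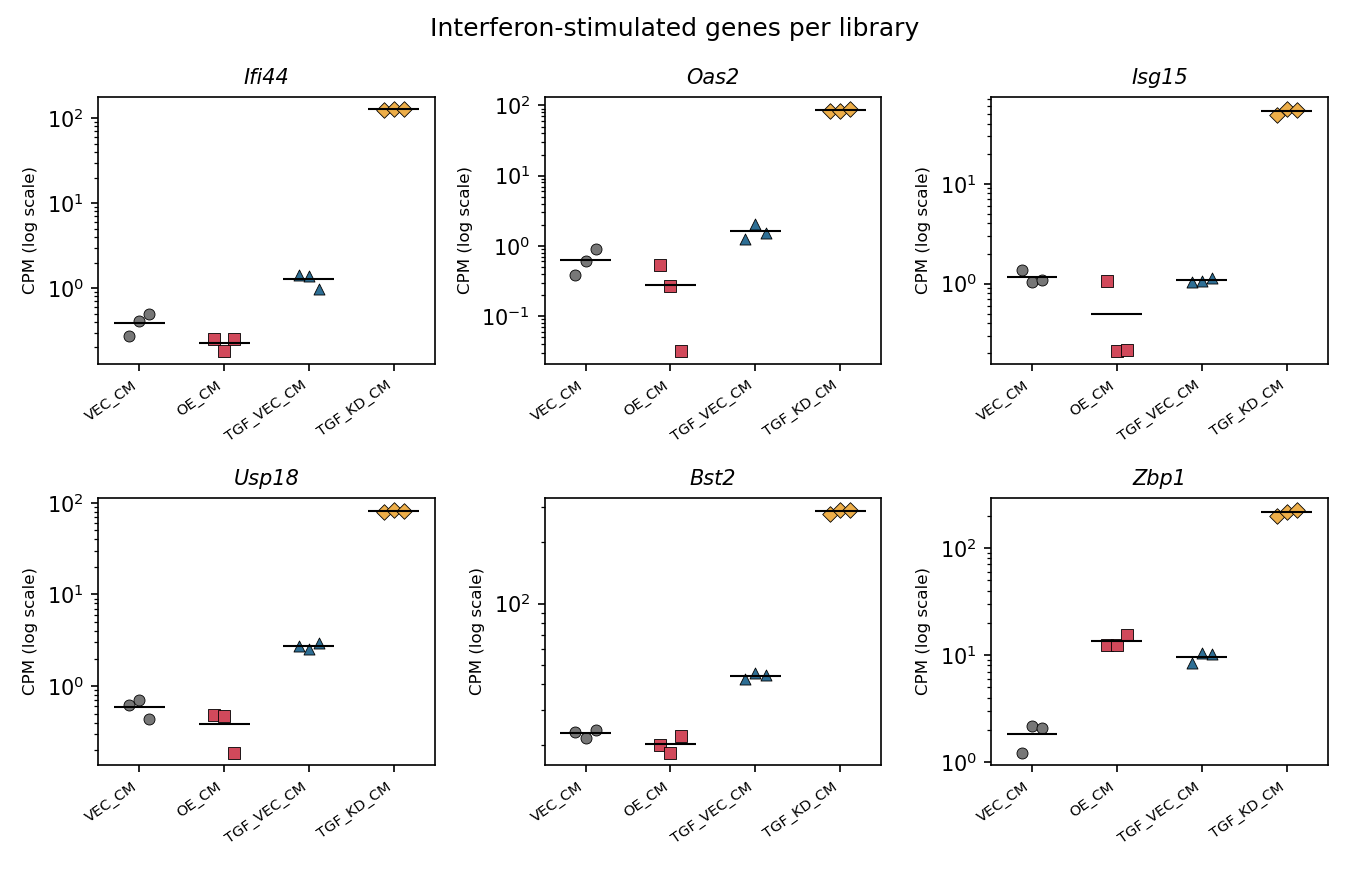
CPM of 6 interferon-stimulated genes in each of the 12 libraries on log axes; points are libraries, and horizontal lines are group means (n = 3). In each panel the 3 TGF_KD_CM libraries lie above the other 9; Ifi44 averaged 127.9 CPM there and 1.27 CPM in TGF_VEC_CM.

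The largest falls by the naming rule were those of Lamb3, a laminin chain (chromosome 1, 193294353 to 193343878, NCBI gene 16780), from 37.1 ± 4.93 to 7.51 ± 0.537 CPM, and Plat, tissue plasminogen activator, from 27.4 ± 0.488 to 6.28 ± 0.935 CPM. Etv5 and Spry4, which are induced by growth factor signalling through ERK, fell by 1.83 ± 0.066 and 1.72 ± 0.13 on the log2 scale, Rap1gap2 by 1.68 ± 0.14 and Vwa1 by 1.58 ± 0.17. Of 21 immediate early genes 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.0284; adjusted p = 0.151 with an estimated correlation). Dusp6, an ERK phosphatase, fell by 1.39 ± 0.092, Ier3 by 0.91 ± 0.1 and Myc by 0.32 ± 0.037, while Fosl2 rose by 0.36 ± 0.03.

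Of 21 TGF-beta responsive genes 10 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.0295; adjusted p = 0.151 with an estimated correlation). The genes of lowest p were Id1, Id2 and Id3, which respond to BMP signals and fell by 1.06 ± 0.056, 1.13 ± 0.078 and 0.67 ± 0.062 on the log2 scale, as they also did in OE_CM, and Smad7 (chromosome 18, 75367365 to 75395935, NCBI gene 17131), at 1.69 times lower. Of 19 endoplasmic reticulum chaperone genes 12 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.00103; adjusted p = 0.621 with an estimated correlation), among them Hyou1 and Manf, each lower by a factor of 1.42, Pdia4 by 1.32 and Hsp90b1 by 1.22. Hypoxia and glycolysis genes had 13 lower and 3 higher of 23, the same adjusted over the list alone (camera adjusted p = 0.0483; adjusted p = 0.687 with an estimated correlation), with Hk1 and Egln3 lower by 1.17 and 1.22 times and Tpi1 1.17-fold higher. This call was lost without TGF_VEC_CM replicate 3 (adjusted p = 0.0657), TGF_KD_CM replicate 1 (0.0695) or TGF_KD_CM replicate 3 (0.0746).

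Of 22 PPAR targets and fatty acid oxidation genes 12 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.0295, or 0.0601 with a filter of 1 CPM in 3 libraries; adjusted p = 0.293 with an estimated correlation). Lpl rose 1.37-fold, from 427.9 ± 9.22 to 584.2 ± 3.58 CPM, Ech1 1.33-fold, the acyl-CoA synthetase gene Acsl1 1.31-fold and Pparg 1.15-fold. Of 21 sterol synthesis genes 12 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0295; adjusted p = 0.621 with an estimated correlation). Insig1, which holds back sterol synthesis, rose 1.86-fold and Srebf2, the transcription factor of the pathway, 1.39-fold. ATF4 targets had 11 higher and 5 lower of 20 (12 and 5 adjusted over the list alone; camera adjusted p = 0.188).

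Matrix genes again went both ways, with 13 of 33 collagens and matrix proteins higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.743). Vcan rose by 0.56 ± 0.035, Col3a1 by 0.34 ± 0.038, Col1a2 by 0.16 ± 0.02 and Fn1 by 0.15 ± 0.021 on the log2 scale; Col16a1 and Col4a2 fell by 0.40 ± 0.025 and 0.36 ± 0.025. Col1a1 was at 1774 ± 46.8 against 1786 ± 25.1 CPM (edgeR adjusted p = 0.74), and Postn, Tgfb1, Il6 and Acta2 did not pass either (adjusted p = 0.778, 0.93, 0.29 and 0.702). Collagen processing genes had 8 higher and 9 lower of 22 (camera adjusted p = 0.564), proteases and inhibitors 7 higher and 4 lower of 19 (0.967), and contractile genes 5 higher and 6 lower of 18 (0.713), each the same adjusted over the list alone; Mmp14 and Ctsk rose 1.43-fold and 1.48-fold. Of 26 cytokines and chemokines 11 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.299), with Ccl2 and Ccl7 both 1.32-fold higher and Lif and Cx3cl1 lower by 1.56 and 1.53 times. Among 17 resting fibroblast markers 7 rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.516); Dpt rose 3.28-fold, Ly6a 2.91-fold and Pdgfrb 1.92-fold.

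Of 7 cartilage and bone genes 5 fell and none rose (camera adjusted p = 0.0483; adjusted p = 0.241 with an estimated correlation), among them Sox9 (-0.97 ± 0.14) and Sp7 (-0.73 ± 0.19). Without TGF_VEC_CM replicate 1 or 3 or TGF_KD_CM replicate 1 or 2 the adjusted p was 0.0656, 0.0732, 0.0621 and 0.0579, with DESeq2 size factors 0.0575 and with a filter of 1 CPM in 3 libraries 0.0601. Of 5 pericyte markers 3 fell and none rose (camera adjusted p = 0.0487; adjusted p = 0.241 with an estimated correlation), with Cspg4 at -0.40 ± 0.023 and Mcam at -0.36 ± 0.046. This call was lost without any of the libraries TGF_VEC_CM 2 and 3 and TGF_KD_CM 1, 2 and 3, at adjusted p from 0.0579 to 0.0805, and with DESeq2 size factors (0.0579). Both lists gave the same counts adjusted over the list alone. With an estimated correlation only the TGF-beta responsive list passed in OE_CM, only the interferon-stimulated list in TGF_KD_CM, and none in TGF_VEC_CM.

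In all, 6229 of 14400 genes passed, 3318 higher and 2911 lower in TGF_KD_CM, and 580 changed at least 2-fold, 216 higher and 364 lower. On log2(FPKM + 1) values without a filter the split was 2336 higher and 3321 lower, and 1507 genes passed a test against a change of 1.2-fold. The excess of falls among genes changed at least 2-fold lies in weak genes, since a filter of 1 CPM in 3 libraries gave 168 higher and 167 lower, and log2(FPKM + 1) values 93 higher and 20 lower.

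TGF_VEC_CM and VEC_CM differ in TGF-beta1 and also in the part of the study, so what follows is the difference between the 2 vector groups. Smad7 rose 2.27-fold, from 10.3 ± 0.289 to 23.5 ± 1.56 CPM (SD, n = 3). Genes of sterol synthesis and uptake fell together, 20 of 21, with Insig1 down from 125.9 ± 9.57 to 12.9 ± 0.607 CPM (log2 -3.29 ± 0.052). Cell cycle genes and oxidative phosphorylation genes were mostly lower, and genes of hypoxia and glycolysis and of endoplasmic reticulum chaperones mostly higher. All 5 list calls were lost with an estimated correlation (adjusted p = 0.0717 for the sterol list and 0.359, 0.359, 0.359 and 0.414 for the others).

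The largest rises by the naming rule were those of Tfr2, a transferrin receptor (chromosome 5, 137569822 to 137588081, NCBI gene 50765), from 2.23 ± 0.32 to 30.2 ± 2.86 CPM, and of Hr, from 6.43 ± 0.427 to 74.7 ± 1.5 CPM. Plat (chromosome 8, 22757722 to 22782848, NCBI gene 18791) rose 11.0-fold, Apol9b 8.81-fold and the RNA-binding protein gene Csdc2 8.15-fold. Beside Insig1 (chromosome 5, 28071412 to 28078662, NCBI gene 231070), large falls were those of Msmo1 (log2 -2.41), the kinase gene Prkcb (-2.35), Tmco4 (-2.30) and Fdps (-2.26).

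The sterol list had a median log2 fold change of -1.43; 20 genes fell over all genes tested and adjusted over the list alone (camera adjusted p = 3.1e-14; adjusted p = 0.0717 with an estimated correlation). Srebf2 fell by 1.78 ± 0.03 and Cyp51, an enzyme of the pathway, by 1.73 ± 0.029 on the log2 scale. Of 35 genes of cell cycle and DNA replication 25 fell and 3 rose (25 and 4 adjusted over the list alone; camera adjusted p = 1.91e-05; adjusted p = 0.359 with an estimated correlation), among them the helicase genes Mcm5, Mcm4 and Mcm7, which fell by 0.69 ± 0.026, 0.56 ± 0.029 and 0.55 ± 0.028, and Cdc20, by 0.94 ± 0.038. Of 22 oxidative phosphorylation genes 15 fell and 3 rose (16 and 3 adjusted over the list alone; camera adjusted p = 0.00826; adjusted p = 0.359 with an estimated correlation), with Ndufs3 and Ndufa9 at -0.49 ± 0.045 and -0.38 ± 0.037. Of 20 NRF2 targets 13 fell and 5 rose, the same adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.292 with an estimated correlation); Fth1, Gstm1 and Pgd fell by 0.85 ± 0.022, 0.73 ± 0.027 and 0.63 ± 0.03 on the log2 scale.

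Hypoxia and glycolysis genes had 16 higher and 2 lower of 23 (camera adjusted p = 0.00306; adjusted p = 0.359 with an estimated correlation), with Vegfa, the vascular growth factor, 2.02-fold and Hk2 1.53-fold higher. Endoplasmic reticulum chaperones had 13 higher and 3 lower of 19 (camera adjusted p = 0.00826; adjusted p = 0.414 with an estimated correlation), with Hyou1 1.72-fold and Manf 1.68-fold higher. TGF-beta responsive genes had 10 higher and 5 lower of 21 (camera adjusted p = 0.016; adjusted p = 0.186 with an estimated correlation), with Skil, Ccn4, Ldlrad4 and Klf10 higher by 2.14, 1.70, 1.80 and 1.42 times. These 3 lists gave the same counts adjusted over the list alone. Interferon-stimulated genes had 17 higher and 2 lower of 28 (17 and 5 adjusted over the list alone; camera adjusted p = 0.0102; adjusted p = 0.359 with an estimated correlation), with Rigi, a sensor of viral RNA, 3.05-fold, Oas3 2.79-fold, Dhx58 2.59-fold and Bst2 1.91-fold higher. Of 13 leukocyte markers 5 were lower, such as Cd14 (log2 -0.69 ± 0.11), none was higher and 8 did not pass, also adjusted over the list alone. The list did not pass camera (adjusted p = 0.139, and 0.547 with an estimated correlation).

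In 6 lists of other cell types more markers rose than fell, but only the pericyte and the cartilage and bone lists passed camera. Weak genes rose as a class here: the median log2 fold change was 0.38 under 1 CPM and -0.04 from 16 CPM up. Camera compares a list with all other genes, not with genes of similar level. Of 15 adipocyte markers 8 fell and 4 rose (camera adjusted p = 0.139). Pericyte markers had 4 of 5 higher (camera adjusted p = 0.0175; adjusted p = 0.193 with an estimated correlation), with Cspg4 at 798.1 ± 12.8 against 565 ± 10.9 CPM, and cartilage and bone genes 6 of 7 (camera adjusted p = 0.0211; adjusted p = 0.218 with an estimated correlation), with Sox9 at 9.71 ± 0.532 against 5.38 ± 0.0818 CPM and Matn3 at 2.17 ± 0.303 against 0.364 ± 0.134 CPM. Endothelial and cardiomyocyte markers each had 3 of 4 higher and none lower (camera adjusted p = 0.252 and 0.231), epicardial markers 2 higher and 1 lower of 4 (0.378) and Schwann cell markers 1 higher of 3 (0.522). Tnnt2, a cardiac troponin gene, was at 109.2 ± 5.85 against 71.9 ± 3.33 CPM and Msln, the mesothelin gene, at 91.3 ± 1.79 against 60.9 ± 3.32 CPM, while the endothelial Pecam1 reached 0.732 ± 0.054 CPM. The call on Pecam1 was lost without VEC_CM replicate 3 (log2 0.85). These 6 lists and the adipocyte list gave the same counts adjusted over the list alone.

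Of the fibroblast readouts, Col1a1 rose 1.37-fold, Postn 2.27-fold and Ccl2 1.58-fold, and Pparg fell by 0.44 ± 0.034 on the log2 scale. Col1a2, Col3a1, Fn1, Tgfb1, Il6 and Acta2 did not pass the test (edgeR adjusted p = 0.982, 0.688, 0.835, 0.18, 0.449 and 0.193). Of 33 collagens and matrix proteins 14 rose and 10 fell (camera adjusted p = 0.285), with Col16a1 1.61-fold and Col18a1 1.41-fold higher and Col6a2 at 149.6 ± 3.57 against 504.7 ± 32.4 CPM. Of 22 collagen processing genes 11 rose and 6 fell (camera adjusted p = 0.0816), with Loxl2 3.63-fold and Tgm2 2.68-fold higher. Contractile genes had 9 higher and 5 lower of 18 (camera adjusted p = 0.24), and proteases and inhibitors 9 higher and 7 lower of 19 (0.405). Cytokines and chemokines had 13 higher and 5 lower of 26 (camera adjusted p = 0.105; 0.0486 with a filter of 1 CPM in 3 libraries), with Lif 3.26-fold and Cx3cl1 2.16-fold higher. Of 16 p53 targets 9 rose and 3 fell (camera adjusted p = 0.189), with Gdf15 2.06-fold higher. The same counts were found adjusted over the list alone for these 6 lists.

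In all, 8396 of 14400 genes passed, 4161 higher and 4235 lower in TGF_VEC_CM, and 1329 changed at least 2-fold, 1047 higher and 282 lower. On log2(FPKM + 1) values without a filter the split was 4876 higher and 3217 lower, and 3575 genes passed a test against a change of 1.2-fold. With a filter of 1 CPM in 3 libraries the genes changed at least 2-fold were 593 higher and 194 lower, and on log2(FPKM + 1) values 146 higher and 54 lower.

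**Figure D3:**
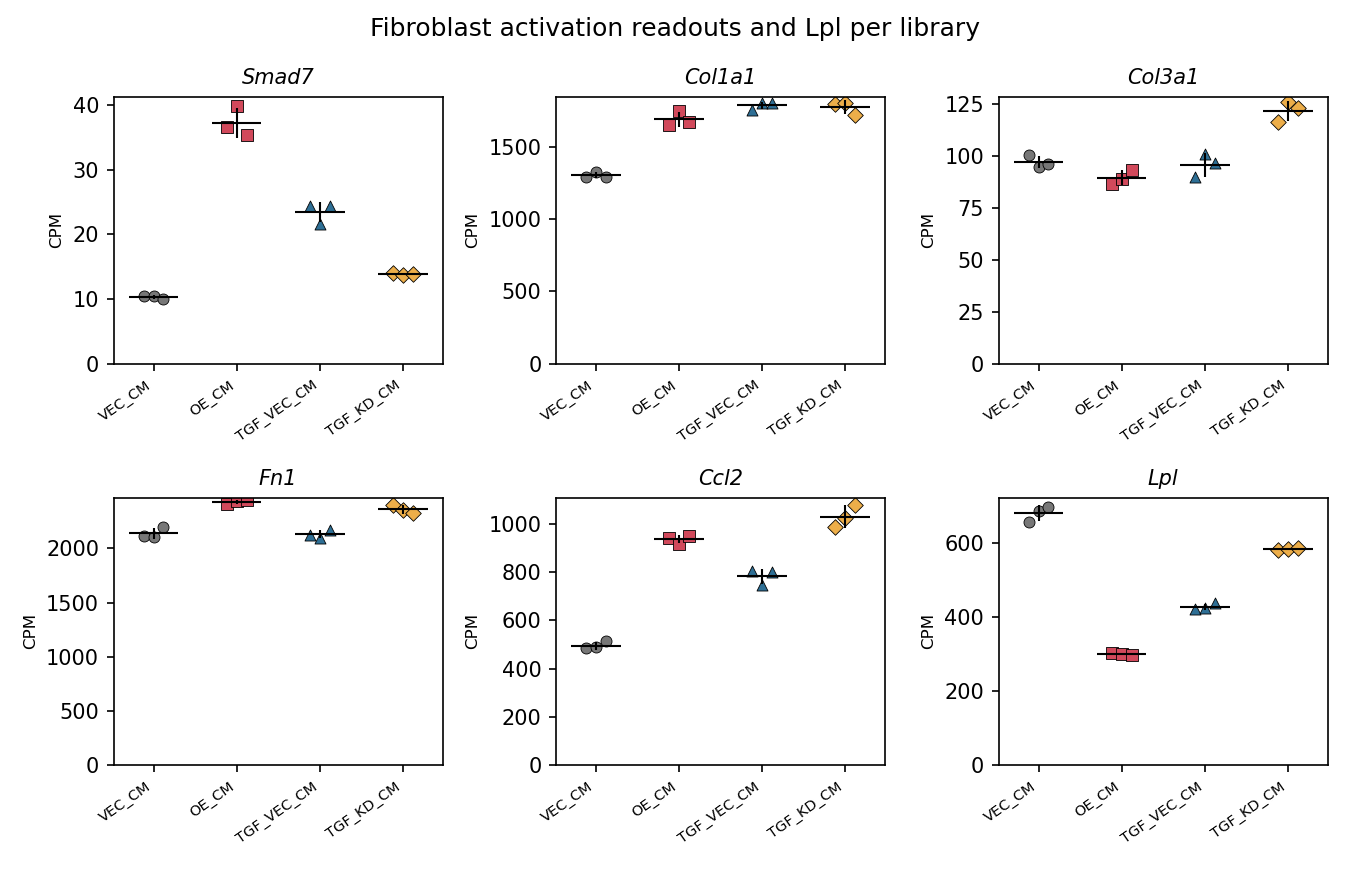
CPM of Smad7, Col1a1, Col3a1, Fn1, Ccl2 and Lpl in each of the 12 libraries, with group means as horizontal lines and SD as vertical lines (n = 3). Smad7 lay at 37.3 CPM in OE_CM and 23.5 CPM in TGF_VEC_CM, above TGF_KD_CM (13.9 CPM) and VEC_CM (10.3 CPM).

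The last question is whether overexpression and inhibition act on the same genes in opposite directions, which the design implies. The clearest such genes were Gpnmb, a glycoprotein gene (chromosome 6, 49036518 to 49058182, NCBI gene 93695), which fell by 0.99 ± 0.024 in OE_CM and rose by 0.94 ± 0.024 in TGF_KD_CM on the log2 scale, Xdh, the xanthine dehydrogenase gene (-1.10 ± 0.029 and 0.87 ± 0.028), Lgals9, a galectin gene (-1.61 ± 0.06 and 1.58 ± 0.048), Lima1 (-0.89 ± 0.026 and 0.59 ± 0.025) and the inflammatory caspase gene Casp4 (-1.15 ± 0.05 and 1.39 ± 0.05). Smad7 moved by 1.85 and -0.76 and Lpl by -1.18 and 0.45. Other genes moved the same way under both: Id1, Id2 and Id3 of the TGF-beta responsive list fell under both, Dpt rose by 2.50 ± 0.07 and 1.72 ± 0.071, the pattern receptor gene Tlr2 by 1.64 ± 0.04 and 0.81 ± 0.039 and Slc11a1, a metal transporter gene, by 0.92 ± 0.028 and 0.78 ± 0.027, while the water channel gene Aqp1 (-1.06 ± 0.027 and -0.65 ± 0.029) and Tinagl1 (-1.01 ± 0.043 and -0.85 ± 0.039) fell under both.

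Of 4096 genes called in both comparisons, 2627 (64.1%) moved in opposite directions. Among the 135 of them that changed at least 2-fold in both, only 75 did. Independent lists would give 825 genes higher in OE_CM and lower in TGF_KD_CM, against 1376 observed, and 851 lower and then higher, against 1251. They would give 941 genes higher in both, against 801, and 747 lower in both, against 668. Across all 14400 genes, which are not independent replicates, the log2 changes correlated with r = -0.056 (Spearman -0.094); with no low-count filter r was 0.003 and with a filter of 1 CPM it was -0.117. No library is shared by these 2 comparisons. The difference between the effects itself passed the threshold for 7553 genes, 3692 more positive in OE_CM and 3861 more positive in TGF_KD_CM.

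Genes that differed between the vector groups tended to move back with inhibition medium. Of 5035 genes called in both, 4646 (92.3%) moved in opposite directions: 2189 were higher in TGF_VEC_CM and then lower in TGF_KD_CM, against 841 for independent lists, and 2457 lower and then higher, against 976. Only 249 were higher in both (959 for independent lists), Ifi44 and Zbp1 among them, and 140 lower in both (856). The correlation across genes was r = -0.53 (Spearman -0.643). The TGF_VEC_CM libraries enter both comparisons with opposite sign, which alone gives a negative correlation: on log CPM the observed r was -0.537 and simulated groups without effects gave -0.497, while the covariance was -0.163 against -0.0163, a difference of -0.146. A group of 3 cannot be divided into separate controls of at least 2 libraries. Part of the excess of opposite genes may therefore come from the shared libraries. The simulations, with their covariance of -0.0163, used only the spread between libraries of a group. A deviation common to the 3 TGF_VEC_CM libraries was not simulated, so the shared part may be larger.

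**Figure D4:**
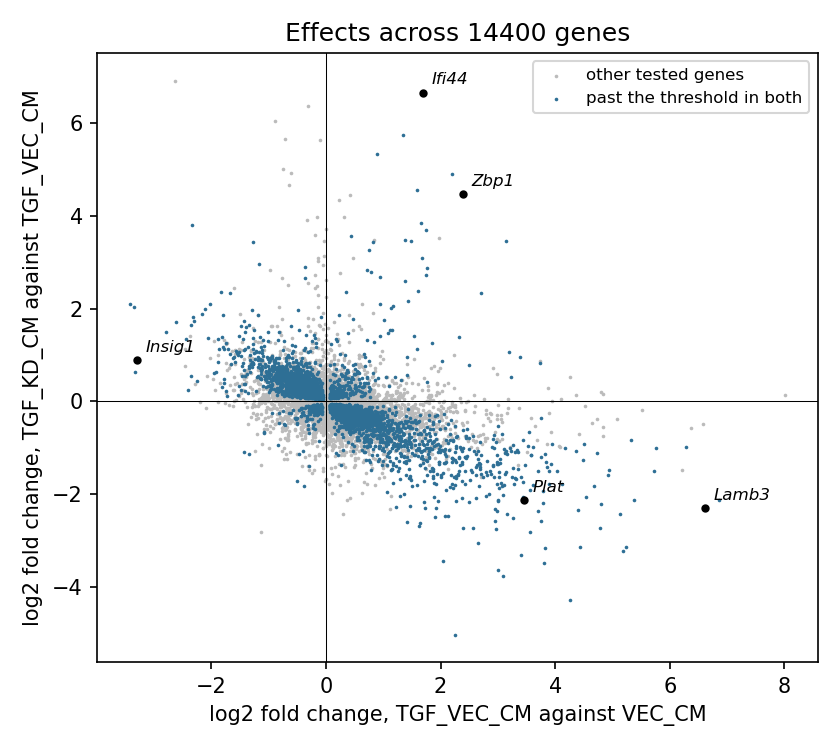
Log2 fold changes of 14400 genes, TGF_VEC_CM against VEC_CM on the x axis and TGF_KD_CM against TGF_VEC_CM on the y axis; each point is a gene, and blue marks the 5035 genes past the threshold in both. Most blue points lie in the quadrants of opposite sign (4646 genes), and Ifi44 and Zbp1 lie at the upper right.

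OE_CM and TGF_VEC_CM differed from VEC_CM in the same direction in many genes. Of 5223 genes called in both, 3622 moved in the same direction, 1916 higher (1180 for independent lists) and 1706 lower (1087), with r = 0.381 (Spearman 0.269). The VEC_CM libraries enter both, and on log CPM the observed r of 0.371 lay below the 0.498 of simulated groups without effects, while the covariance was 0.137 against 0.0166, a difference of 0.121. These controls, too, are 3 libraries and cannot be divided, so part of the excess of genes moving alike may come from them. A deviation common to the 3 VEC_CM libraries was not simulated either. Hr, Loxl2 and Tgm2 rose in both comparisons and Col6a2 and Timp2 fell in both, whereas Srebf2 was at 290.9 CPM in OE_CM, near its level of 300.6 CPM in VEC_CM.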

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

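The tests of the interferon response were chosen after the result was seen, and the splits of the libraries before.

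The effects of overexpression and of inhibition medium differed between the 2 parts of the study, and this difference is what singled out the following results. It passed the threshold for 7553 genes, and 5 lists passed the camera test on it, of which only 2 passed with an estimated correlation, the TGF-beta responsive and the interferon-stimulated genes (adjusted p = 0.0341 for both), while PPAR targets (0.0856), sterol synthesis genes (0.438) and ATF4 targets (0.438) did not. The median difference (OE effect minus KD effect, log2) was 0.57 in TGF-beta responsive genes, -3.61 in interferon-stimulated genes, -0.48 in PPAR targets, -0.34 in sterol synthesis genes and 0.32 in ATF4 targets. Opposite interventions should differ, but only 1 of the 2 was applied with TGF-beta1, so the size of the difference cannot be given to the microRNA alone. Of 100 splits that mix the labels within each part, 1, the real one, gave as many genes, and the highest other gave 3874, a split that keeps the real groups of one part. Mixing groups that differ in many genes widens the spread within the mixed groups, so this rank says little about chance.

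The 27 of 28 interferon-stimulated genes that rose with inhibition medium had a list median far above that of any other list in this comparison. Leukocytes among the cells would raise leukocyte markers, whose median log2 change was -0.38, which argues against that explanation. Scaling moved the median of all genes by at most 0.024, against a list median of 3.51, which argues against scaling. The 4 interferon genes that were counted, with interferon gamma left out, had 1 count in TGF_KD_CM and 2, 6 and 4 counts in VEC_CM, OE_CM and TGF_VEC_CM. Interferon made by the fibroblasts is left open, since interferon RNA may have passed before harvest and interferon gamma was not counted. The design gives inhibition medium as the biological explanation, but interferon carried in the medium and a reaction to the introduced RNA could not be told apart.

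For comparisons of 3 with 3 libraries the 10 splits are too few to exclude chance. For genes, 1 of 10 splits, the real one, reached the count in OE_CM against VEC_CM (7778), 1 of 10 in TGF_KD_CM against TGF_VEC_CM (6229) and 1 of 10 in TGF_VEC_CM against VEC_CM (8396), and the highest other split gave 0 each time. The other splits mix groups that differ in many genes, which widens the spread within the mixed groups, so their 0 calls say little about chance. For lists, 2 of 10 splits reached the 4 of OE_CM against VEC_CM (highest other 5), and 1 of 10 the 9 and the 10 of the other comparisons (highest other 5 in both).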

How the results depend on the processing

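Counts of all genes past the threshold kept within 1.5 times of their value under every other setting except the test against 1.2-fold, which by construction asks for more and gave 3078 (OE), 1507 (KD), 3575 (TGF) and 4091 (difference) genes. Genes changed at least 2-fold fell from 1059, 580, 1329 and 1406 to 210, 113, 200 and 490 on log2(FPKM + 1) and 456, 196, 446 and 784 on log2(FPKM + 0.1), which shrink changes of weak genes. Leaving out single libraries gave 7176 to 7366, 5576 to 5820, 7810 to 7940 and 7237 to 7367 genes. Among named genes 6565 comparisons were counted as the same, 12 gained and 111 lost the call. Of genes called in the main fit 0 reversed, while a change of sign in a gene not called there was not counted. For single lists 805 kept their side of the threshold, 45 gained and 38 lost the call. The number of lists was 1 (OE), 1 (KD) and 0 (TGF) with an estimated correlation, 21, 19 and 25 with fry, and 25, 23 and 26 with its mixed form, against 4, 9 and 10. The OE and KD correlation was 0.003 with no low-count filter, where its sign turned, -0.117 with a filter of 1 CPM, -0.158 on log2(FPKM + 1), and -0.052 to -0.022 without single libraries; that of TGF and KD was -0.476, -0.47 and -0.557 to -0.527 for the last 3. The cause was not tested. With the replicate number as a block 7894, 6381, 8521 and 7678 genes passed and 5, 8 and 10 lists; the leukocyte list gained its call in OE (0.0432), the pericyte list lost it in KD (0.0564), and no other list call changed. The 18 same-numbered pairs correlated with r from -0.0372 to 0.0436, and 11 of 12 libraries lay closest to their own number, a hint from the data, not the design. Depth limits genes near 0.0939 CPM.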

Other observations

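The tests in this part were chosen after the results were seen, except the splits of the libraries, which were set before.

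Some fibroblast markers were low in all 12 libraries, and others were expressed. Of 21 resting fibroblast markers with counts, 14 averaged at least 1 CPM, among them Ddr2 (441 CPM), Pdgfra (169 CPM), Dpep1 (46.7 CPM) and Dpt (27.6 CPM), and Postn, a gene of activated fibroblasts, averaged 1.79 CPM. Among low markers, Thy1 averaged 0.322 CPM, Dcn, the decorin gene, 0.134, Cd34 0.0527, Clec3b 0.044, Lum, the lumican gene, 0.00689, Acta2 0.445 and Tagln 0.202 CPM. Col1a2 averaged 4510 CPM, Vim 2540 and S100a4 2510 CPM. The proliferation gene Mki67 averaged 1480 CPM, while the cell cycle inhibitor genes Cdkn2a and Cdkn2b had 9 and 10 counts over all libraries, next to Mtap with 2136. Sex chromosome genes were low as well. Xist, on the X chromosome, averaged 0.147 CPM, and the Y chromosome genes Ddx3y, Eif2s3y, Kdm5d and Uty 0.0551, 0.0821, 0.0391 and 0.0278 CPM.

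Posterior HOX genes, which mark the rear of the body axis, were expressed: Hoxc10 averaged 97.4 CPM, Hoxa10 57.1, Hoxb9 30.2 and Hoxb13 7.35 CPM. Of 7 transcription factors of heart mesoderm only Tbx18 (11.2 CPM) and Gata4 (2.88 CPM) reached 1 CPM, and Tbx5, Tbx20 and Gata6 stood at 0.0119, 0.00226 and 0.00475 CPM.

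Too few reads would hide markers, but 3 counts stood for at most 0.0939 CPM in any library, below the level of Thy1 and Acta2, which argues against depth. Cells from a rear body region, or an established line from one, would show posterior HOX genes, and 7 of 11 reached 1 CPM in every library, which goes with that explanation. These genes do not tell whether the cells are a line. The test cannot separate those possibilities or exclude heart cells changed by culture, and no biological explanation was tested, since all groups share the cells. Until the source is known, the low Acta2, Tagln and Ccn2 levels may limit what these libraries can say about myofibroblasts.

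TGF_VEC_CM had 1047 genes at least 2-fold higher than VEC_CM and 282 lower, 609 and 102 of them under 1 CPM. Scaling is an unlikely cause, since the lowest ratio of rises to falls under 3 scalings was 3.71. An even background of reads, as from DNA, would lift silent genes alike. The genes that rose at least 2-fold had a median gain per kilobase 58.7 times the mean gain of chemoreceptor genes. The latter ranged from -0.00184 to 0.0102 CPM per kilobase between libraries, and 1043 of the 1047 gained more than its highest value. A background of the chemoreceptor size is too small to give that median gain. The genes were chosen for having risen, however, which itself raises their gain, so nothing follows for weak genes with smaller gains. The share of weak genes was 390 CPM higher in TGF_VEC_CM (1397 ± 26.9) than in VEC_CM (1007 ± 5.51), but it also differed within the parts, with 802 ± 20.9 in OE_CM and 1145 ± 27.6 in TGF_KD_CM, so the measure is not specific to parts run separately, which stays open because part and TGF-beta1 coincide. The biological explanation the design gives is TGF-beta1, which may be the cause but could not be set apart from the part.

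The correlation of OE and KD effects (r = -0.056) was matched by 8 of 100 splits of the libraries within each part, the real one included, the highest other being -0.0777. These splits keep part of the real effects, so they cannot decide whether a correlation of this size arises without effects. On log CPM the observed r was -0.0685, and 20 simulated data sets without effects gave -0.00364 ± 0.017 (SD). Genes were simulated independently of each other, so that spread may be too narrow. The correlations that share libraries (on log CPM -0.537 for TGF and KD and 0.371 for TGF and OE) were matched by 47 of 100 regroupings for TGF and KD (highest other -0.8654) and 75 of 100 for TGF and OE (highest other 0.8713), the real one included in each. The regroupings mix groups with real effects, so they decide nothing about these correlations. Simulated groups without effects gave covariances of -0.0163 and 0.0166, against -0.163 and 0.137 observed. Those simulations hold only the spread between libraries of a group, not a deviation common to the shared controls.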
